A study of Drosophila melanogaster with 6 samples.

How the data were processed

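Global run-on sequencing (GRO-seq) maps RNA polymerases that are engaged on DNA: isolated nuclei extend their nascent RNA with a labelled nucleotide, and the labelled RNA is purified and sequenced. The cells were Schneider line 2 (S2) cells of Drosophila melanogaster, an embryonic line with features of blood cells, kept at 25 °C in medium with 10% serum, per the labels. The run-on used 5-bromo-UTP and 1 µM CTP, and the labelled RNA was captured on beads that carry an antibody against the bromo base. Of the 6 samples in the series, 5 were used: untreated cells, cells given control double-stranded RNA against β-galactosidase (mock RNAi), cells given double-stranded RNA against the NELF-B and NELF-E subunits of the negative elongation factor (NELF RNAi), and a pair of run-ons with and without the detergent sarkosyl. RNAi lasted 96 hours, per the labels. The remaining sample, labelled only by its circularization enzyme, was not analysed here.

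Each group was 1 library. Per the labels, 4 of the 5 libraries pooled 2 replicate experiments and the plus-sarkosyl library held 1. The untreated, mock and NELF libraries were made by ligating adapters to both RNA ends. The sarkosyl libraries went through 3 bead enrichments and a circularization protocol, so library protocol and sarkosyl series cannot be separated from each other. No group could therefore be tested against another, and no p-values were computed.

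The deposited tracks held 1 signal track per strand and library, with a value at single positions. The values were in RPM, reads scaled by the authors to a fixed library total, per the file headers and the values themselves, and the minus-strand tracks carried the same unit with a negative sign. Within a library every value was a whole multiple of a single step, the RPM value of 1 read, whose inverse gave a whole number of reads, so whole reads were recovered for 100% of values in each library (tolerance 0.001 of a read). The authors' denominators recovered in this way were 12469277 reads (untreated), 12676609 (mock RNAi), 11635189 (NELF RNAi), 4942028 (plus sarkosyl) and 4249570 (minus sarkosyl). The tracks held 10254253, 10196824, 8646456, 4071947 and 2978406 of these reads, or 82.2%, 80.4%, 74.3%, 82.4% and 70.1% of the denominators. The reads that make up the rest of each denominator were not analysed here. Whether positions were removed from some of the libraries before deposit is not given in the sources used here, so a position with 0 reads can be absent or removed. The submitters' processing notes name Bowtie for the sample without files; for the 5 libraries used, the aligner, its settings, the genome build and the end of the read that was placed are not given in the sources used here. Start coordinates were read as counted from 1, so positions can be off by 1 bp.

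Names and ends of the sequences in the tracks (chromosome 2L to 23011545, chromosome 3R to 27905054) differ from those of the gene table used for symbols (genes to 23416153 and 32068441, Release 6), and the sequence names are those of Release 5 of the fly genome. Coordinates were therefore not joined to genes, and no gene names are given. The rule set for this case before the data were examined was used: transcribed units were called from the tracks. Signal on 12 placed sequences was summed in 50-bp bins per strand over the 5 libraries, each scaled to the same total. Bins in the top 10% were merged across gaps of up to 500 bp, which gave 20279 stretches, and the 5466 stretches of at least 2000 bp were kept as units (median length 4100 bp). The first 250 bp of a unit stood for the promoter-proximal window and the part beyond +400 for the body. A unit is not a gene: it can join neighbouring genes, miss a start or begin at a bin boundary. The levels of NELF-B and NELF-E were not analysed here, and neither were the gene lists set beforehand.

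The pausing ratio was the read density of the promoter-proximal window over that of the body, for units with at least 20 reads in each. Comparisons used units with a mean of at least 20 reads over the 2 libraries in each window. Ratios were taken on the log2(value + pseudocount) scale with a pseudocount of 1 read, which understates changes of units with few reads. A unit was counted when it differed at least 2-fold, a rule of size and not a test. The ratio of a named unit carries an exact conditional binomial (Clopper-Pearson) 95% interval without pseudocount. Medians carry 95% order-statistic intervals over units, which are not replicates. Intervals of ratios and of shares cover counting error only and treat every read as independent. PCR copies are not independent molecules, so these intervals can be too narrow, most of all where 1 position holds many of the reads. The named units were the 5 highest and the 5 lowest ratios in each window among the upper 50% of mean signal, and 3 each way for mock RNAi against untreated. Groups of units (pausing ratio in the untreated library, chromosome, length) were set beside 10000 random lists of the same size drawn from 20 classes of signal level. Those groupings were chosen after the data were seen, except for the limits of 2, 5 and 10 on the pausing ratio. Upstream antisense signal was taken 500 bp upstream on the opposite strand, for starts with no opposite-strand unit start within 1000 bp.

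The steps were tested on simulated data that were simpler than the tracks. Units were planted far apart, each with a start peak and an even body on a low background. Counts for the ratios were drawn from a Poisson distribution, without strong single positions. The rates below therefore cover counting error only. Of 200 planted units 200 were found, at a median of 22.5 bp from the planted start. With counts drawn for NELF RNAi against mock RNAi over 4040 units, 100% of units planted at 4-fold and 48.5% of those planted at 2-fold passed the 2-fold rule, and 0.573% and 0.26% of unchanged units did so in the runs with 2-fold and 4-fold planting. For plus against minus sarkosyl (2753 units), 100% and 48% of the planted units passed, with 0.588% and 0.509% of unchanged units. For mock RNAi against untreated (4026 units), 100% and 45% passed, with 0.235% and 0.497% of unchanged units. The intervals covered the planted ratio in 95.5% and 96.1% of units for NELF RNAi against mock RNAi. Alternatives covered the scaling between libraries, both windows, the filter on low values, the pseudocount, the fold threshold and the antisense window. After the data were seen, a limit of 10 reads per position, a stricter bin threshold, shifted starts and isolated starts were added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.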

Results

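Engaged RNA polymerase was mapped by GRO-seq in S2 cells in 5 libraries, 1 per group: untreated, mock RNAi, NELF RNAi, plus sarkosyl and minus sarkosyl. The authors' read totals ranged from 4249570 (minus sarkosyl) to 12676609 (mock RNAi), so 1 read was worth 0.235 RPM in the shallowest library and 0.0789 RPM in the deepest. NELF, the negative elongation factor, holds polymerase shortly after initiation, and sarkosyl strips proteins from chromatin so that held polymerases can extend their RNA in the run-on. The comparisons followed from this design: NELF RNAi against mock RNAi, plus against minus sarkosyl, and mock RNAi against untreated as a measure of how far libraries without NELF knockdown differed. There were no replicates of any group, so no difference below could be set against replicate error. All coordinates are in the build of the tracks, whose sequence names are those of Release 5, and were not joined to gene annotation.

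In every library the summed sense signal was highest within 100 bp of unit starts, on the inside. Starts were called from the summed signal of these same libraries, so low signal outside and higher signal just inside are partly fixed by the call. The call can also raise the pausing ratio, since the first bin must pass while bodies may hold gaps of up to 500 bp. The median pausing ratio was 1.72 in the untreated library (95% interval over units 1.63 to 1.77, 3975 units), 1.84 in mock RNAi (1.76 to 1.91, 4088 units) and 1.86 in NELF RNAi (1.77 to 1.94, 3991 units). It was 4.94 with sarkosyl (4.74 to 5.14, 3147 units) and 2.71 without (2.59 to 2.81, 1789 units). Because the units that reached 20 reads differed between libraries, the 1634 units that did so in all 5 were also compared: their medians were 3.44, 3.85 and 3.46 in the untreated, mock and NELF libraries, 8.44 with sarkosyl and 2.83 without. A pausing ratio of at least 10 was found for 11.4% of units in the untreated library, 11.8% in mock RNAi, 9.35% in NELF RNAi, 25.4% with sarkosyl and 6.04% without. Promoter-proximal windows held 10.3% of the reads on the placed sequences in the untreated library (exact binomial 95% interval 10.2 to 10.3), 10.8% in mock RNAi (10.8 to 10.8) and 8.84% in NELF RNAi (8.82 to 8.86). With sarkosyl they held 14.3% (14.2 to 14.3) and without it 4.90% (4.88 to 4.93).

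**Figure D1:**
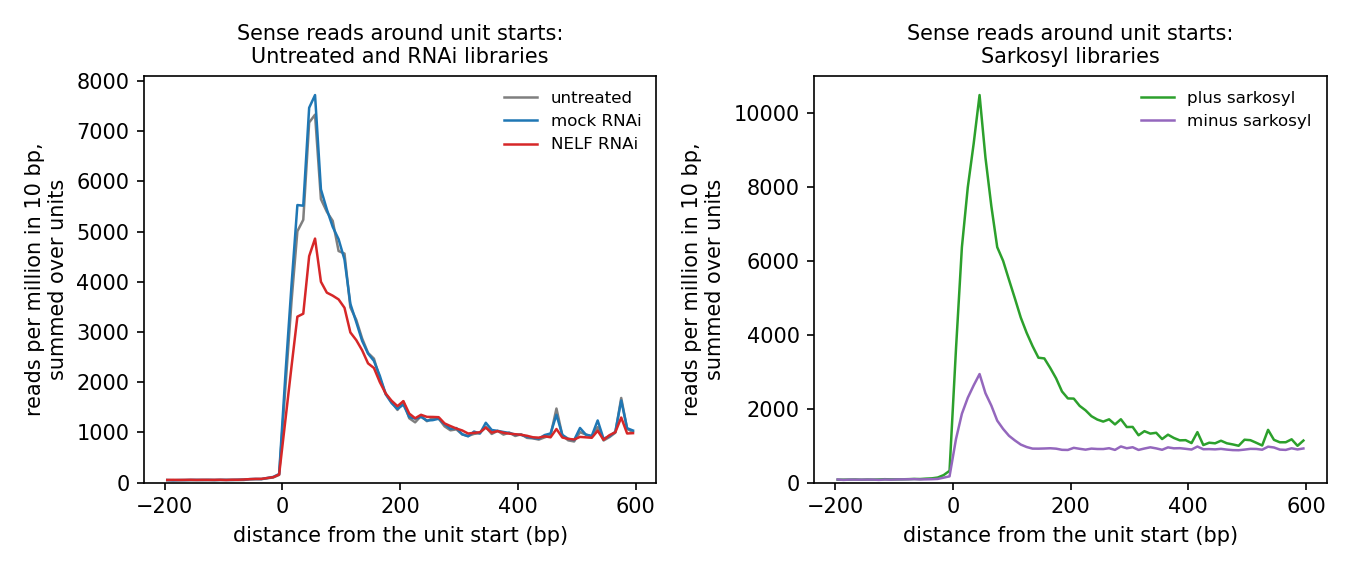
Sense signal in RPM per 10 bp, summed over 5466 units, against the distance from the unit start in bp; the left panel shows the untreated and RNAi libraries and the right panel the sarkosyl libraries, 1 line per library. The NELF RNAi line lies below the mock line over the first 100 bp (ratio 0.599 over the first 50 bp) and meets it near +200, and the plus-sarkosyl line lies above the minus-sarkosyl line throughout the promoter-proximal window.

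Upstream antisense signal was measured at starts with no opposite-strand unit start nearby. Its median, as a percent of the promoter-proximal sense reads of the same start, was 2.18% in the untreated library (1.70 to 2.64, 2633 starts), 2.63% in mock RNAi (2.22 to 3, 2676 starts) and 3.08% in NELF RNAi (2.52 to 3.45, 2573 starts). With sarkosyl it was 2.04% (1.64 to 2.44, 1903 starts) and without it 1.59% (1.09 to 2.22, 1145 starts). The pooled percentages were higher, between 10.7% without sarkosyl and 15.2% in NELF RNAi. The promoter-proximal sense reads they are divided by were lower in NELF RNAi than in mock RNAi, and higher with than without sarkosyl. The percentages therefore do not show how antisense signal itself differed. The medians depended on the filter against opposite-strand unit starts, which were called from these same tracks. With all starts kept the medians were 7.69%, 8.33% and 9.33% in the untreated, mock and NELF libraries, 9.20% with sarkosyl and 4.55% without, and the pooled percentages ran from 17.8% to 29.3%.

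NELF RNAi against mock RNAi asked how loss of NELF alters polymerase near starts and in bodies. Promoter-proximal signal was at least 2-fold lower in the NELF library at 179 of 4040 units and at least 2-fold higher at 50, while bodies were 2-fold lower at 23 and 2-fold higher at 5. For 76 of the lower windows and none (0) of the higher ones the counting interval lay wholly beyond 2-fold. The median log2 ratio was -0.12 in promoter-proximal windows (-0.13 to -0.099) and -0.048 in bodies (-0.055 to -0.042). With libraries scaled to the same total signal these medians shifted by 0.12, to -0.0011 and 0.068, and the split became 128 lower and 76 higher; setting the median body ratio to 0 gave 156 and 64. Counting at most 10 reads per position, which limits the strongest positions of both libraries, gave 54 lower and 50 higher. Bins in the top 5% gave 80 and 28, and no filter on low values 270 and 180.

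The difference followed the pausing ratio in the untreated library, which took no part in the ratio. The 453 units with a pausing ratio of at least 10 had a median log2 promoter-proximal ratio of -0.61 (-0.66 to -0.55), a fold of 0.654; 91 of them were 2-fold lower and 0 higher. This median lay below all 10000 random lists of matched signal, whose middle 95% spanned -0.46 to -0.40. With at most 10 reads counted per position the median of these 453 units was -0.20 (-0.23 to -0.16). Units with ratios of 5 to 10 had a median of -0.34 (-0.40 to -0.29), with 27 of 349 2-fold lower and 0 higher. Units with ratios of 2 to 5 had a median of -0.17 (-0.19 to -0.14), with 19 of 951 lower and 3 higher. For the 2287 units below 2 it was 0.039 (0.019 to 0.062), with 42 lower and 47 higher. The median of the 5 to 10 class lay below the middle 95% of its random lists (-0.29 to -0.21). That of the class below 2 lay above it (-0.028 to -0.0096), but that of the 2 to 5 class lay within it (-0.17 to -0.12). Bodies did not follow this order: their medians were -0.052, -0.045, -0.031 and -0.056 from the lowest to the highest class, and each becomes positive when libraries are scaled to the same total.

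**Figure D2:**
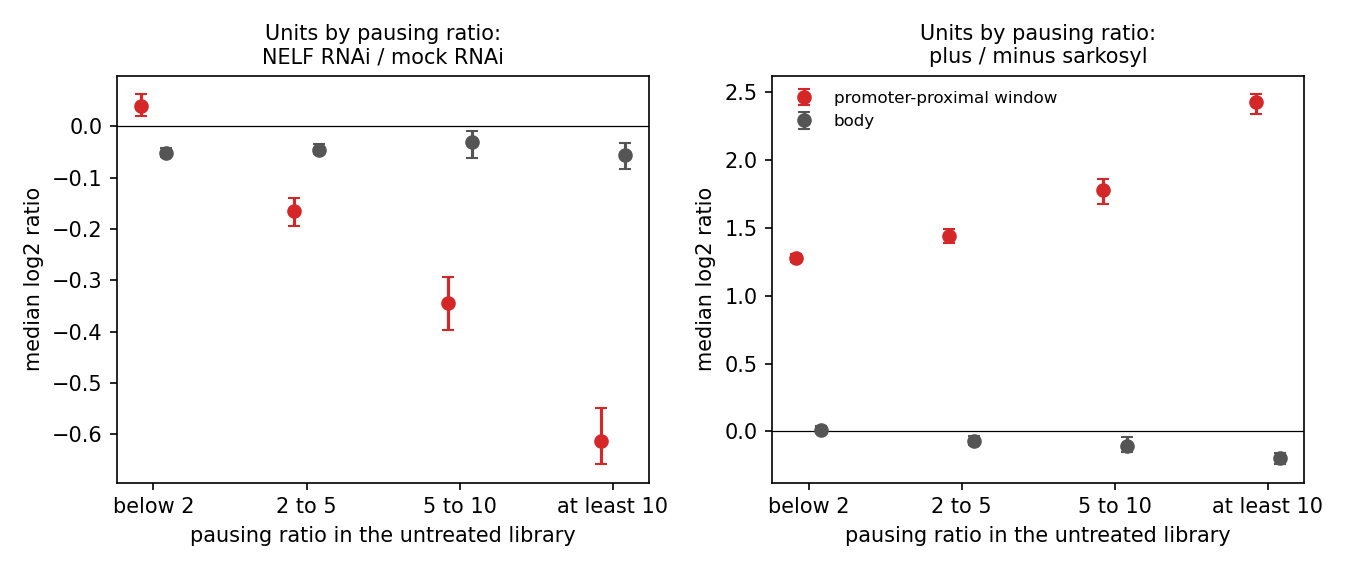
Median log2 ratio of promoter-proximal windows (red) and bodies (grey) for units grouped by their pausing ratio in the untreated library; bars are 95% order-statistic intervals over units, the left panel is NELF RNAi over mock RNAi and the right panel plus over minus sarkosyl. Promoter-proximal medians run from 0.039 to -0.61 on the left and from 1.28 to 2.43 on the right, and body medians lie between -0.20 and 0.0096 in both panels.

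Within the promoter-proximal window the lower signal lay close to the start. Summed over all units, the NELF library held 0.599 of the mock signal in the first 50 bp, 0.692 from there to +100, 0.863 from +100 to +150, 0.984 from +150 to +200 and 1.04 from +200 to +250. These sums give most weight to units and positions with many reads. The same total per library adds 0.12 to each log2 ratio, which lifts the ratio from +150 to +200 above 1 and leaves those nearer the start below 1. The median share of window reads in the first 100 bp was 45.5% in NELF RNAi and 52.2% in mock RNAi. With the window shortened to 100 bp, 322 of 2558 units were at least 2-fold lower and 14 higher, and the median log2 ratio over units was -0.41 (-0.43 to -0.39). Of the 179 units with lower windows, 151 (84.4%) also had a body ratio below 1, against 62.5% of all 4040 units, and their median log2 body ratio was -0.20. With the same total per library 119 of them (66.5%) did so, against 33.7% of all units, and the median was -0.084. In 14 of the 179 the body was 2-fold lower as well.

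The lowest promoter-proximal ratio among the better covered units was at 3R 22809051 to 22814250 (minus strand), with 594 reads in mock RNAi and 125 in NELF RNAi, a fold of 0.229 (0.188 to 0.278). Next came 2R 12716551 to 12724450 (plus strand) at 0.242 (0.187 to 0.309) and 3R 14735601 to 14738650 (minus strand) at 0.259 (0.236 to 0.284). The unit at 3R 6995901 to 6998400 (minus strand) was at 0.269 (0.233 to 0.309), and that at 3R 8816001 to 8818950 (minus strand) at 0.276 (0.249 to 0.306). A single position held 76.8% of the mock reads at 3R 6995901, 67.4% at 2R 12716551, 39.8% at 3R 14735601, 38.9% at 3R 22809051 and 10.1% at 3R 8816001. The pausing ratios of these 5 units in untreated cells ran from 6.26 to 123. All 5 bodies were also below 1, at log2 -0.16 and -0.19 for the first and second unit and -0.95 or less for the others. There were 209 mock and 90 NELF body reads at 3R 14735601, 107 and 27 at 3R 6995901, and 191 and 90 at 3R 8816001. With at most 10 reads counted per position, 2R 12716551 and 3R 8816001 were no longer 2-fold lower (log2 -0.71 and -0.75), and the other 3 windows lay between -1.36 and -1.13. The highest ratios were smaller and came from units with pausing ratios below 2: 2L 6920651 to 6931300 (plus strand) at 2.21 (1.63 to 3.03) and 3R 7235801 to 7242700 (plus strand) at 1.95 (1.45 to 2.64), followed by 2R 10242351 to 10246100 (minus strand) at 1.86 (1.62 to 2.13), 3R 27039851 to 27045300 (minus strand) at 1.86 (1.57 to 2.20) and 2L 8083401 to 8088000 (plus strand) at 1.85 (1.37 to 2.51). At 2R 10242351 the body also differed, with 1710 mock and 2519 NELF reads, but the untreated library, at 2351 body reads, was close to the NELF library.

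**Figure D3:**
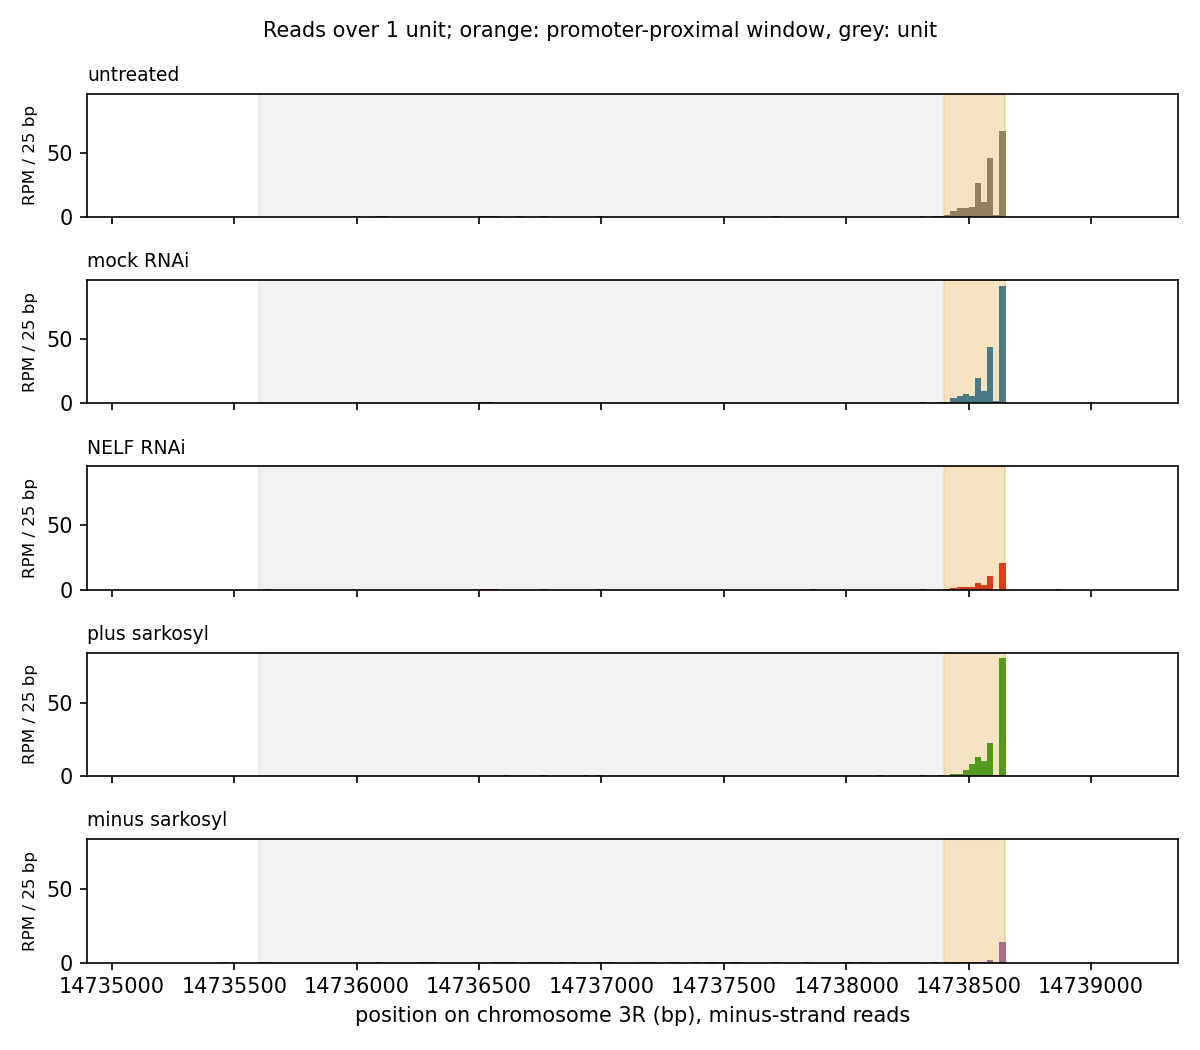
Minus-strand signal in RPM per 25 bp over the unit at 3R 14735601 to 14738650, 1 panel per library; the orange band is the promoter-proximal window, the grey band the rest of the unit, and the upper 3 and the lower 2 panels each share an axis. The window held 191 RPM in mock RNAi and 49.5 RPM in NELF RNAi, and 144 RPM with and 18.8 RPM without sarkosyl.

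The lowest bodies in NELF RNAi were X 17801751 to 17806100 (plus strand) at a fold of 0.338 (0.313 to 0.364), 3L 17611751 to 17614700 (minus strand) at 0.382 (0.361 to 0.404), 3R 7805451 to 7808400 (minus strand) at 0.393 (0.352 to 0.437), 2R 10760851 to 10764450 (plus strand) at 0.400 (0.376 to 0.426) and 3L 9085651 to 9088700 (plus strand) at 0.410 (0.386 to 0.436). In each of them a single position held a large part of the mock body reads, from 39.7% at 3R 7805451 to 74.5% at X 17801751. With at most 10 reads counted per position none (0) of the 5 was 2-fold lower, at log2 ratios from -0.71 at 3R 7805451 to -0.27 at X 17801751. With bodies taken beyond +1000, the units at 2R 10760851 and 3L 9085651 were at -0.64 and -0.48. The highest bodies had no such position, with at most 1.92% of reads at one place: 2R 1573151 to 1579500 (minus strand) at 2.05 (1.87 to 2.25), X 11498351 to 11505700 (minus strand) at 2.05 (1.88 to 2.24), 2R 17533651 to 17540750 (plus strand) at 1.81 (1.64 to 2.01), 3R 17135701 to 17146700 (plus strand) at 1.75 (1.62 to 1.88) and 3R 22158401 to 22163400 (plus strand) at 1.66 (1.53 to 1.81). At X 11498351 and 2R 17533651 the promoter-proximal log2 ratios were -0.41 and -0.59 while the body ratios were 1.03 and 0.86. The others did not go this way: their promoter-proximal log2 ratios were 0.067 at 2R 1573151, 1.04 at 3R 17135701 and 0.57 at 3R 22158401.

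Plus against minus sarkosyl asked how much engaged polymerase extends its RNA only in the detergent. Promoter-proximal signal was at least 2-fold higher with sarkosyl at 2108 of 2753 units (76.6%) and at least 2-fold lower at 10, and for 1177 of the higher windows the counting interval lay wholly beyond 2-fold. The median log2 ratio was 1.51 (1.47 to 1.55), a fold of 2.84, against -0.064 in bodies (-0.083 to -0.044), where 69 units were 2-fold higher and 10 lower. Scaling to the same total shifted these ratios by -0.24 and left no excess of higher bodies, with 38 higher and 42 lower. Setting the median body ratio to 0 gave 76 higher and 6 lower bodies. With no filter on low values the count of lower windows was 387 of 5368. Summed over units, the plus library held 3.45 times the minus signal in the first 50 bp, 4.14 times from +100 to +150, 2.14 times from +200 to +250 and 1.14 times from +400 to +1000.

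Here too the size followed the pausing ratio in untreated cells. The median log2 promoter-proximal ratio was 2.43 (2.34 to 2.48) for the 447 units with a pausing ratio of at least 10, of which 439 were 2-fold higher, above all 10000 random lists of matched signal (middle 95% 2.08 to 2.21). It was 1.78 (1.68 to 1.86) for the 339 units at 5 to 10, with 287 higher, 1.44 (1.39 to 1.49) for the 709 units at 2 to 5, with 558 higher, and 1.28 (1.24 to 1.31) for the 1258 units below 2, with 824 higher. Here again the 2 to 5 class lay within the middle 95% of its random lists (1.43 to 1.53). The 5 to 10 class lay above it (1.53 to 1.70) and the class below 2 below it (1.34 to 1.38). Body medians ran the other way, from 0.0096 (-0.014 to 0.041) below 2 to -0.20 (-0.24 to -0.16) at 10 and above, and all are negative with the same total per library.

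The largest promoter-proximal ratios were at 2R 14682051 to 14690050 (minus strand), with 1153 reads with and 50 without sarkosyl, a fold of 19.8 (14.9 to 26.9), and at 2R 4537101 to 4542750 (plus strand), with 1299 and 60 reads, a fold of 18.6 (14.4 to 24.5). In the first 100 bp of the former window neither library had reads, so the shorter window gave only the ratio of the pseudocounts (log2 -0.22). Then followed 3R 20093451 to 20097000 (minus strand) at 16.4 (11.8 to 23.5), 3R 22806201 to 22812750 (plus strand) at 15.0 (11.8 to 19.3) and 2R 2880151 to 2882750 (plus strand) at 15.3 (9.27 to 27.2), where 16 reads without sarkosyl limit the precision. In the NELF comparison the unit at 2R 2880151 had 402 promoter-proximal reads in mock RNAi and 140 in NELF RNAi. Of these highest windows it alone was at least 2-fold lower in the NELF library. Mock and NELF windows held 138 and 75.3 RPM at 2R 14682051, and 539 and 383 RPM at 2R 4537101. They held 334 and 278 RPM at 3R 20093451, and 278 and 165 RPM at 3R 22806201.

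The lowest promoter-proximal ratios with sarkosyl rested in most cases on single positions. At 3L 20764351 to 20771100 (plus strand) the fold was 0.0572 (0.0384 to 0.0823), and 458 of the 466 reads without sarkosyl were at 1 position, while the untreated, mock and NELF libraries had 1 read each in this window. At 2R 17070351 to 17081400 (plus strand), with a fold of 0.131 (0.0997 to 0.170), a single position held 92.3% of the reads without sarkosyl, and at 2R 15612951 to 15615800 (minus strand), with 0.236 (0.187 to 0.295), 53.3%. At X 14618101 to 14620950 (plus strand), with 0.438 (0.309 to 0.616), it held 96.2%, and the window had 0 reads in the untreated, mock and NELF libraries, which allows up to 0.241, 0.237 and 0.258 RPM if no positions were removed before deposit. The unit at 3L 8650551 to 8669000 (minus strand), with 0.536 (0.390 to 0.733), had no such position. The first 4 were no longer 2-fold lower with at most 10 reads counted per position, at log2 ratios of -0.47, -0.42, -0.99 and -0.12.

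The lowest bodies with sarkosyl were led by 3R 5330651 to 5338800 (minus strand) at a fold of 0.276 (0.270 to 0.282), where 1 position held 93.9% of the reads without sarkosyl; with at most 10 reads counted per position its log2 ratio became 0.089. The unit at X 3267151 to 3285050 (plus strand), at 0.454 (0.438 to 0.470), had 72.7% of its reads at 1 position and a log2 ratio of -0.40 under the same limit. Those at 3R 19555751 to 19558750 (minus strand), 2L 3056551 to 3070000 (plus strand) and X 6140001 to 6149550 (minus strand), at 0.454 (0.378 to 0.544), 0.479 (0.460 to 0.499) and 0.486 (0.407 to 0.578), had at most 7.10%. The last 2 of these fell just short of 2-fold with the median body ratio at 0 (log2 -0.998 and -0.975). The highest bodies were 2R 11196051 to 11198650 (minus strand) at 7.26 (6.28 to 8.42), 3L 15502701 to 15507300 (plus strand) at 6.83 (5.94 to 7.87), 3L 16948601 to 16952200 (plus strand) at 4.37 (3.76 to 5.09), 3R 14806751 to 14810000 (plus strand) at 3.87 (3.18 to 4.72) and 3R 14913701 to 14920650 (minus strand) at 3.78 (3.26 to 4.40). All 5 of these had pausing ratios below 2 in untreated cells. They ran from 0.022 at 3R 14806751 (3 promoter-proximal and 2030 body reads) to 1.49 at 3L 16948601 (327 and 2814 reads). A start missed by the call would leave its peak in the body, so a low ratio here need not mean an unpaused gene. The strongest position held 12.9% (3R 14913701) to 30.8% (3L 16948601) of the body reads with sarkosyl. The unit at 3R 14913701 reversed, to a log2 ratio of -0.37, when the body was taken beyond +1000.

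By chromosome, the 42 units of chromosome 4 had a median log2 body ratio of 0.40 (0.25 to 0.50) with sarkosyl, above all random lists of matched signal (-0.18 to 0.11). The 28 units of the heterochromatic sequences had one of 0.41 (0.20 to 0.47), also above all random lists (-0.19 to 0.15). The 349 units of chromosome X were at -0.20 (-0.26 to -0.15), below all random lists (-0.11 to -0.020). The promoter-proximal median of chromosome 4 was 1.02 (0.78 to 1.31), below that of all other units (1.52). That of the heterochromatic sequences was 0.80 (0.56 to 1.29).

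Mock RNAi against untreated gave fewer 2-fold differences than NELF RNAi against mock RNAi. At least 2-fold lower promoter-proximal signal was found for 17 of 4026 units and higher signal for 31, and no body (0) differed 2-fold either way. With the same total per library these counts became 13 and 40, and with the median body ratio at 0 they became 12 and 45. The median log2 ratio was 0.098 (0.087 to 0.11) in promoter-proximal windows and -0.060 (-0.066 to -0.056) in bodies. The median log2 ratio of the pausing ratios, 0.15 (0.14 to 0.17), lay farther from 0 than in the NELF comparison, -0.061 (-0.084 to -0.046), as did the promoter-proximal median with the same total per library (0.13 against -0.0011). At the 454 units with a pausing ratio of at least 10 in untreated cells the promoter-proximal median was 0.057 (0.035 to 0.083), with 2 lower and 0 higher. Bodies of the 54 units of chromosome 4 had a median of -0.13 (-0.16 to -0.079), below the middle 95% of random lists (-0.10 to -0.025), and those of the 44 units of the heterochromatic sequences one of -0.11 (-0.16 to -0.089). The lowest windows were 2R 10790951 to 10795550 (minus strand) at a fold of 0.462 (0.352 to 0.601), 2R 13318501 to 13322850 (plus strand) at 0.513 (0.355 to 0.732) and 3R 16149251 to 16153750 (minus strand) at 0.518 (0.415 to 0.644). The first of these was at a log2 ratio of -0.86 with at most 10 reads counted per position. The highest were 2R 17070351 to 17081400 (plus strand) at 2.51 (2.11 to 3), where 1 position held 89.3% of the mock reads, 3L 14530751 to 14534500 (plus strand) at 2.22 (1.56 to 3.20) and chromosome 4 at 89951 to 97150 (plus strand) at 2.17 (1.58 to 3.01). The same limit took 2R 17070351 to a log2 ratio of 0.53. The most different bodies were 3R 14958151 to 14962600 (plus strand) at 0.684 (0.621 to 0.753), 2R 10242351 at 0.715 (0.672 to 0.762) and 3L 597301 to 604050 (minus strand) at 0.746 (0.681 to 0.816). On the higher side were 2L 3046751 to 3049450 (plus strand) at 1.44 (1.32 to 1.57), 3R 6087801 to 6090950 (plus strand) at 1.37 (1.29 to 1.46) and 3R 25695051 to 25703400 (plus strand) at 1.34 (1.27 to 1.41); single positions held 50.2% and 34.5% of the mock reads of the last 2.

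**Figure D4:**
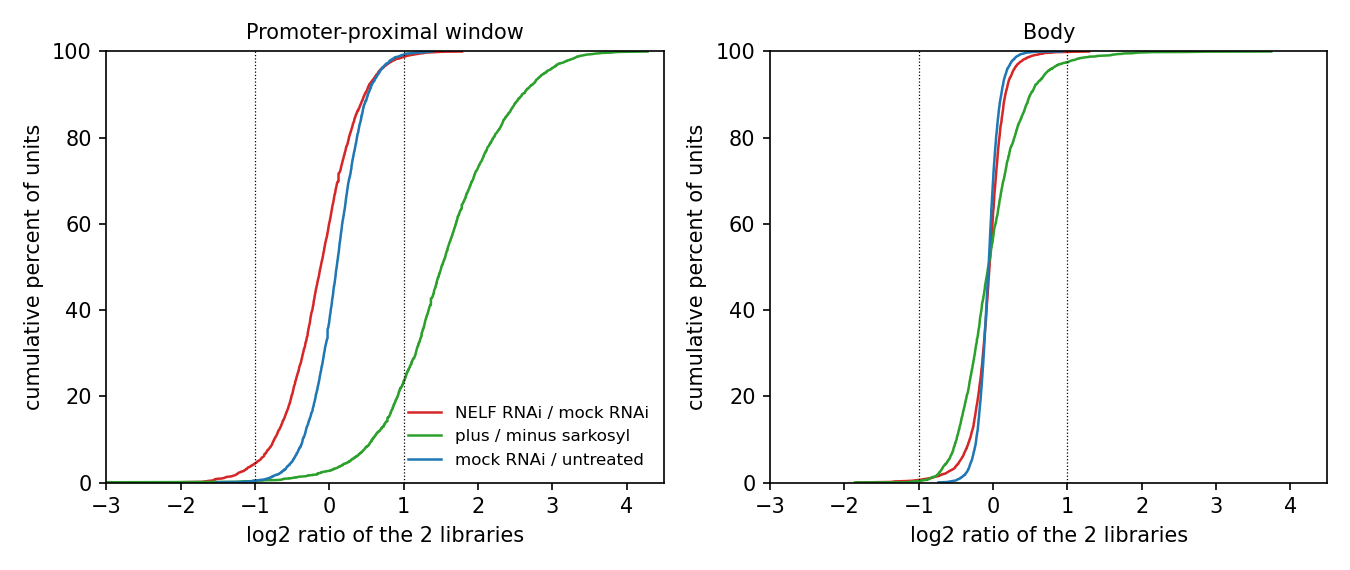
Cumulative percent of units against the log2 ratio in promoter-proximal windows (left) and bodies (right) for the 3 comparisons, 1 line each; dotted lines mark 2-fold. In promoter-proximal windows the plus over minus sarkosyl line is centred at 1.51 and the other 2 lie at -0.12 (NELF RNAi over mock RNAi) and 0.098 (mock RNAi over untreated), while body medians lie between -0.064 and -0.048.

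Across the 3656 units with a mean of at least 20 reads over the 5 libraries, which are not independent replicates, the 10 pairs of libraries fell by protocol. Pearson's r of log2 RPM for promoter-proximal windows and bodies was 0.98 and 1.00 for mock and untreated, 0.96 and 0.99 for mock and NELF RNAi, and 0.89 and 0.96 for the sarkosyl pair. Between protocols r was lower: untreated and plus sarkosyl had 0.61 in promoter-proximal windows (Spearman's rho 0.62) and 0.70 in bodies (rho 0.81). Ratios between libraries were therefore taken only within a protocol.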

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

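Of the tests below, those on library scaling, on any pair of libraries and on pooled experiments were chosen after the result was seen; the others had their bounds written before, and that without the 5 highest positions was added once the value with at most 10 reads per position was known. Signal outside the sequences used for the comparisons was seen in every library. The mitochondrial sequence held 0.0593% of track reads in the untreated library (exact binomial 95% interval 0.0578 to 0.0608), 0.0678% in mock RNAi (0.0662 to 0.0694) and 0.0753% in NELF RNAi (0.0734 to 0.0771), and, in the other protocol, 0.00231% with sarkosyl (0.00187 to 0.00282) and 0.00567% without (0.00485 to 0.00660). The unplaced sequences U and Uextra held 0.441%, 0.487% and 0.615% in the untreated, mock and NELF libraries, and 1.12% and 1.30% in the plus- and minus-sarkosyl libraries.

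The first pattern weighed was the lower promoter-proximal signal in the NELF RNAi library at the 453 units with a pausing ratio of at least 10. A single scaling factor would move windows and bodies alike, but the log2 promoter-proximal ratio minus the log2 body ratio had a median of -0.51 (-0.57 to -0.48), which argues against scaling. With at most 10 reads counted per position the median was -0.20 (-0.23 to -0.16), which missed the bound set against strong positions (an interval wholly below -0.2); that limit saturates the strongest positions in both libraries, and in the test added afterwards, without the 5 highest positions of each window, chosen in the untreated library and holding a median of 36.0% of the mock reads, it was -0.42 (-0.47 to -0.39), so a few positions carried part of the difference and not all of it. Mock RNAi against untreated gave 17 units 2-fold lower where NELF RNAi gave 179, but with 1 library per group a difference between any pair of libraries cannot be told apart from an effect of the knockdown. A loss of held polymerase after NELF depletion is a hypothesis that stays open beside it.

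The second pattern was the higher promoter-proximal signal with sarkosyl. The median log2 promoter-proximal ratio minus the log2 body ratio was 1.55 (1.51 to 1.59), which argues against scaling, and with at most 10 reads per position the ratio was 1.44 (1.41 to 1.47), which argues against a few positions with very many reads. The plus library held 1 experiment and the minus library 2 pooled experiments, so the experiment and the detergent cannot be told apart.

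The third pattern was the higher body signal of the 42 chromosome 4 units with sarkosyl, whose median log2 ratio exceeded that of all other units by 0.47 (bootstrap 95% interval 0.32 to 0.57). With at most 10 reads per position the excess was 0.48 (0.33 to 0.58), and with bodies taken beyond +1000 it was 0.45 (0.31 to 0.55), which argues against strong positions and against reads of the start peak. The median lay at percentile 100 of random lists of matched body signal, which argues against signal level. The pattern was not particular to chromosome 4. The 28 units of the heterochromatic sequences had a similar body median of 0.41 (0.20 to 0.47), also at percentile 100 of their random lists. Chromosome 4 bodies also stood apart, by less and the other way, in mock RNAi against untreated (median -0.13, -0.16 to -0.079, against -0.060 for other units; random lists -0.10 to -0.025), but not in NELF RNAi against mock RNAi (-0.025, within random lists at -0.093 to 0.0061), so a shift of these bodies between libraries stays open, as does 1 experiment against 2; no biological explanation was tested.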

How the results depend on the processing

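The limit of 10 reads per position, bins in the top 5% (stricter bins), starts moved to the highest bin, isolated starts (no same-strand stretch ending within 2000 bp upstream) and starts without an opposite-strand stretch were chosen after the data were seen. Values are given in the order NELF RNAi against mock RNAi, plus against minus sarkosyl, mock RNAi against untreated. The cause of a change was not tested unless it is stated. Median promoter-proximal log2 ratios of -0.12, 1.51 and 0.098 became -0.0011, 1.27 and 0.13 with the same total signal per library, -0.069, 1.57 and 0.16 with the median body ratio at 0, and -0.41, 1.80 and 0.15 in a window of 100 bp. For the first and second comparison they became -0.088 and 1.02 with no filter and -0.25 and 2.01 with at least 80 reads; for the second, 1.34 with a pseudocount of 5 reads. With at most 10 reads per position they were -0.046 and 1.44, with bins in the top 5% -0.066, 1.33 and 0.048, and with starts moved to the highest bin -0.073, 1.40 and 0.062; isolated starts gave 0.13 for mock RNAi against untreated. The median body ratio of NELF RNAi against mock RNAi reversed from -0.048 to 0.068 with the same total per library, a scaling that adds 0.12 to every log2 ratio. The direction of this median thus depends on the library total that is chosen.

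Counts of units 2-fold lower and higher in promoter-proximal windows were 179 and 50 for NELF RNAi. They became 322 lower and 14 higher in the window of 100 bp, 270 and 180 with no filter, 641 and 270 at a threshold of 1.5-fold, and 80 and 28 with stricter bins. With the same total they became 128 and 76. The higher count became 1 with at least 80 reads, 33 with a pseudocount of 5 and 32 at isolated starts. The lower count became 54 with at most 10 reads per position. For sarkosyl (10 lower, 2108 higher) the lower count became 6 in the window of 100 bp, 387 with no filter, 3 with at least 80 reads, 25 at 1.5-fold, 6 with at most 10 reads per position, 32 with stricter bins and 4 at isolated starts. The higher count, 2108 of 2753 in the main setting, became 801 of 910 with at least 80 reads and 1374 of 2079 with stricter bins. Fewer units were compared in both, but the share that was 2-fold higher rose in the former and fell in the latter. For mock RNAi against untreated (17 and 31) the counts became 116 and 128 with no filter, 1 and 3 with at least 80 reads, 7 and 15 with a pseudocount of 5, 129 and 295 at 1.5-fold, 11 and 18 with stricter bins, and 2 and 13 at isolated starts. Of 105 such medians and counts of promoter-proximal signal over the 3 comparisons, 48 were classed as near their main value and 57 as moved. Counts carry no interval, so for them this class is no statistical limit. The change from 179 to 128 lower units, for example, was classed as near.

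Median pausing ratios, in the order untreated, mock, NELF, plus and minus sarkosyl, became 3.40, 3.75, 3.37, 9.88 and 6.11 in the window of 100 bp, 1.17, 1.28, 1.31, 2.47 and 1.34 with no filter, 4.13, 4.26, 4.10, 10.7 and 5.92 with at least 80 reads, and 1.27, 1.35, 1.39, 4.04 and 2.01 with stricter bins. They became 5.37 and 3.04 for the sarkosyl pair with bodies beyond +1000. Moved starts gave 1.80, 1.91, 1.97 and 4.56, and isolated starts 2.02, 2.19, 2.16 and 5.27, for all but the minus-sarkosyl library. In every one of these settings the median was higher with than without sarkosyl. Upstream antisense medians became 0.391%, 0.602%, 0.659%, 0.433% and 0% within 250 bp, 7.69%, 8.33%, 9.33%, 9.20% and 4.55% with all starts kept, and 0.127%, 0.288%, 0.336%, 0.121% and 0% without an opposite-strand stretch, a restriction that removes starts with antisense signal by construction.

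Of the named units, 3 values reversed: the window of 2R 14682051 to -0.22 within 100 bp, where neither library had reads, the body of 3R 14913701 to -0.37 beyond +1000, and the body of 3R 5330651 to 0.089 with at most 10 reads per position, as 1 position held most of its reads. The other 465 values of named units kept their direction, 56 of them outside their counting interval. No paired analysis was possible because each group was 1 library. The alternatives on annotated starts and on overlapping genes could not be run without annotation of the build. Depth limited how many units could be compared, which were 4040, 2753 and 4026. Simulated changes planted at 2-fold, the threshold itself, passed the rule in 48.5%, 48% and 45% of units.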

Other observations

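The tests in this part were chosen after the data were seen, although the bounds of the test on bodies were written before its value. Stretches too short to count as units, of 100 to under 2000 bp, also differed in their first 250 bp; they had to reach 100 reads where units needed 20, so the sizes are not set side by side. Among the 729 with a mean of at least 100 reads in their first 250 bp, the median log2 ratio of NELF RNAi over mock RNAi was -0.58 (-0.68 to -0.52), and 219 of them (30.0%) were at least 2-fold lower and 0 higher. Mock RNAi over untreated gave 0 lower and 2 higher among 781. With sarkosyl the median was 2.74 (2.63 to 2.83) over 438 stretches, with 369 (84.2%) 2-fold higher and 37 lower. The rule on unit length thus left out 219 short stretches at which the NELF library was 2-fold lower.

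The promoter-proximal ratios of the NELF and sarkosyl comparisons, which share no library, were inversely ordered across units: Spearman's rho was -0.43 (Pearson's r -0.42) over 2568 units, and -0.17 (r -0.22) for bodies. These are correlations across units, which are not independent replicates, and both ratios followed the pausing ratio in untreated cells.

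Of the 766 units of at least 10000 bp, 439 had a mean of at least 20 reads in every window along them in the sarkosyl pair. Their median log2 ratio was 1.61 (1.52 to 1.70) in the promoter-proximal window, -0.14 (-0.23 to -0.073) between +400 and +1000, -0.22 (-0.27 to -0.15) from there to +2000, -0.25 (-0.32 to -0.18) to +4000, -0.30 (-0.35 to -0.26) to +7000 and -0.31 (-0.36 to -0.22) to +10000. Of these body windows, the intervals of the first and of that ending at +7000 did not overlap, and those of neighbouring windows did. The same units were measured in every window and differences within units were not taken, so this overlap does not show whether neighbouring windows differed. For NELF RNAi over mock RNAi 600 units did so, with 0.052 (0.019 to 0.079) between +400 and +1000, -0.033 (-0.059 to -0.0067) from there to +2000, -0.030 (-0.055 to -0.0042) to +4000, -0.048 (-0.064 to -0.031) to +7000 and -0.033 (-0.057 to -0.012) to +10000, and the last 4 become positive with the same total per library. Mock RNAi over untreated, with no knockdown, showed a decline of similar size over 597 units, from 0.040 (0.021 to 0.073) in the first of these windows and 0.0013 (-0.024 to 0.024) in the next to -0.078 (-0.093 to -0.058), -0.069 (-0.082 to -0.052) and -0.062 (-0.083 to -0.048).

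Position 5334365 of 3R (minus strand) held 29021 reads without sarkosyl (6829 RPM) and 7839 with it, and position 7050728 of X (minus strand) held 21781 and 1676; both had 0 reads in the untreated, mock and NELF tracks, and whether they were absent from those libraries or removed before deposit is not known. The strongest position of the untreated library, 3R 19857081 (minus strand), held 6498 reads there, 5028 in mock RNAi, 2008 in NELF RNAi, 5 with sarkosyl and 2 without. The 10 strongest positions held 3.11% of the track reads without sarkosyl and 0.873% with it, against 0.259% to 0.433% in the other 3 libraries.

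A candidate explanation for the 23 bodies that were 2-fold lower in NELF RNAi was another start peak inside the unit, since units can join neighbouring genes. Without the 250 bp of each body that held most reads in the untreated library (a median of 42.9% of body reads), 14 of the 23 were still 2-fold lower, between the bounds set for and against the explanation, so it cannot be told apart from lower signal along the whole body. With sarkosyl, the 18 of these units that could be compared had a median log2 body ratio of 0.15 (-0.12 to 0.86), against -0.070 (-0.088 to -0.050) for the other 2550.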
